A study of Drosophila melanogaster with 8 samples.

How the data were processed

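Gene expression was measured in S2 cells, a Drosophila melanogaster line with features of blood cells (hemocytes), on Affymetrix arrays. Per the labels' protocols, cells received double-stranded RNA (dsRNA) that was either non-specific (control) or directed at dSTING, the fly homologue of STING, and 3 days later were transfected with a double-stranded DNA (dsDNA) of 90 nucleotides or mock transfected. They were lysed 24 hours after that, and total RNA was labelled with biotin by a 3' in vitro transcription kit. The 8 arrays form 4 groups of 2: control mock, control dsDNA, dSTING RNAi mock and dSTING RNAi dsDNA. Groups follow the titles and source names, which are alike in all samples. In 4 samples the genotype tag says otherwise, because it follows the DNA treatment instead of the RNAi.

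The deposited table gives 1 intensity per probe set and array on a linear scale, as processed by the authors. The software, background correction and normalization behind it are not given in the sources used here. The values themselves never lie under 1. Between 19.6% and 24.1% of the values of an array lie exactly at that floor, the median intensity of an array was 1.18 to 1.23, and the mean was 21.7 to 22.5. The sorted values of the arrays nearly coincide, as a between-array normalization would leave them, but none is described. At the floor of 1 values carry no order, and adding 1 compresses fold changes near it. No scanner files were used here.

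Of 18952 probe sets, 183 control probe sets (AFFX), some of them for fly transcripts, were left out and 18769 were tested. Platform annotation, updated through gene identifiers against the Release 6 plus ISO1 MT assembly of the fly genome, gave 13647 probe sets 1 gene, 402 several genes and 4720 no name. Of those with 1 gene, 13544 were matched by identifier, and 11983 genes had at least 1 probe set. No coordinates are given, since the table names no genome build.

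Values were analysed as log2(intensity + 1), so fold changes are on that scale and understate the change of dim probe sets. One limma model (version 3.58.1, in R 4.3.3) with a mean for each of the 4 groups was fitted to all 8 arrays, with lmFit, contrasts.fit and eBayes. It had 4 residual degrees of freedom, which the prior raised to 5.32. In all, 7 contrasts were taken from it: the knockdown in dsDNA-treated cells, the knockdown in mock-treated cells, dsDNA in control cells, dsDNA in knockdown cells, the difference between the last pair (interaction), and the mean knockdown and mean dsDNA effects with 4 arrays on each side. Tests were two-sided, Benjamini-Hochberg adjustment ran over all probe sets of a contrast, and the threshold was an adjusted p of 0.05. Ratios are of mean intensities, and SDs are over the 2 arrays of a group. The labels do not say whether 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, whatever its source. The number of arrays limits the precision.

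The design, the named genes, the gene lists and most alternatives were set before the data were examined. Genes were named by a fixed rule: Sting first, then for each contrast the 10 genes with the smallest unadjusted p wherever fewer than 5 probe sets passed the threshold (which was so for every contrast), described as not past it. For each list the 2 members with the smallest p were taken as values. The 27 lists held immune and signalling pathways (STING and cGAS-like receptors, antimicrobial peptides, Imd, Toll, JAK/STAT, JNK and stress), nucleic acid pathways (RNA interference, DNA damage and p53, nucleic acid degradation and nucleotides), proteostasis (heat shock, unfolded protein response, autophagy and lysosome, proteasome, ribosomal proteins), metabolism (lipid synthesis and storage, glycolysis, mitochondrial respiration, detoxification and oxidative stress), apoptosis, cell cycle, ecdysone response, hemocyte markers, and markers of cells that an S2 culture should not hold (fat body, muscle, neuron and glia, germline and follicle, gut). Lists were tested with camera in limma at a preset correlation of 0.01, with 1 probe set per gene, and adjusted over the 27 lists of a contrast. List values cover the measured members only. Coverage was low for ribosomal protein genes (41 of 93, 44.1%) and heat shock genes (11 of 23, 47.8%). Members were also adjusted over the list alone. That adjustment does not count the 27 lists searched in a contrast, so members of some lists can pass it by chance. camera with an estimated correlation and fry were run beside it.

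Alternatives were the replicate number as a block, quantile normalization, centring each array on its median, a filter that kept the 9384 probe sets above the median level, eBayes with trend and robust options, 1 probe set per gene, array weights, log2(intensity + 16), only the arrays compared, a 2-group model for the mean effects, and leaving out each array in turn. Chosen after seeing the data were a filter on a mean log2 level above 3 (4189 probe sets), leaving out the 2 arrays that stood apart, the first component of the residuals as a covariate, a crossed block, and list tests with Sting taken out of the data and of every list. Principal components and array correlations used the 4189 probe sets above that level. Pearson correlation was 0.983 to 0.996 in the 4 pairs of arrays of the same group and 0.972 to 0.996 in the 24 pairs from different groups. No pair shared more than 0.183% identical values, so no array is a copy of another.

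The procedure was tested on simulated data made from the real group means and spread. With 200 probe sets changed at a time, the limma test over 18769 probe sets was run for the knockdown in dsDNA-treated cells. It recovered 61.7% of changes of 1 on the log2 scale (617 of 1000) and 98.6% of changes of 3 (986 of 1000). Over the same 10 runs it made 125 false calls. With only 4 probe sets lowered by 1.5, it recovered 48%, against 77% over the 4189 brighter probe sets. A simulated list of 40 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 10 of 10 runs. Because the simulated genes varied independently, this does not show how the list tests behave on the real arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and plots.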

Results

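The 8 arrays measured transcripts in S2 cells in a design of 4 groups, each with 2 arrays: control or dSTING RNAi, each with mock transfection or with dsDNA for 24 hours. The series set out to find how knockdown of dSTING affects expression in cells given dsDNA. Genes that mark blood cells were present: the GATA factor srp had a mean intensity of 43.7 over all arrays, the scavenger receptor crq 23.6, and 15 of 28 measured hemocyte markers lay above a log2 level of 3. Genes of other cell types were mostly low, with 0 of 8 fat body, 0 of 10 muscle, 0 of 10 neuronal and glial and 0 of 8 gut markers above that level, although elav reached 6.78 and Apoltp 6.42 in single arrays. Of 9 germline and follicle markers only tud, which encodes a Tudor domain protein, lay above it. One array of the control mock group (number 2) and one of the dSTING RNAi dsDNA group (number 2) stood apart, at 12.2 and -12.5 on a first principal component that held 52.1% of the variance.

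**Figure D1:**
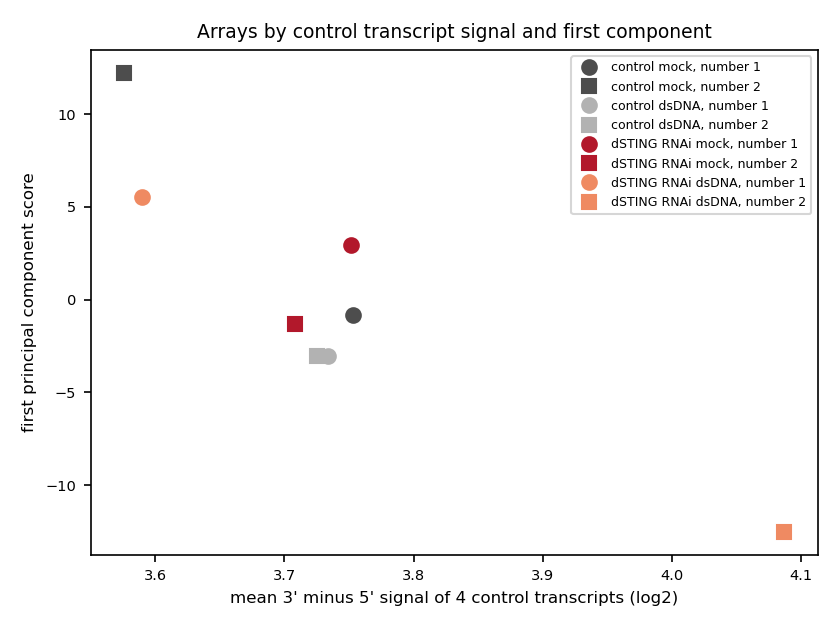
Each point is 1 array, with the mean log2 difference of 3' over 5' probe sets of 4 control transcripts on the x axis and the score on the first principal component on the y axis. The 2 arrays at the ends are control mock number 2, at 3.58 and 12.2, and dSTING RNAi dsDNA number 2, at 4.09 and -12.5.

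Sting (CG1667), which encodes the cyclic dinucleotide receptor that the dsRNA targeted, was low in all 4 dSTING RNAi arrays. Its intensity was 49.8 ± 1.56 in control mock cells and 52.4 ± 1.09 in control dsDNA cells (SD, n = 2 each). It was 4.89 ± 2.04 in dSTING RNAi mock cells and 6.69 ± 1.93 in dSTING RNAi dsDNA cells (SD, n = 2 each). The 4 control arrays ranged from 48.7 to 53.1 and the 4 RNAi arrays from 3.45 to 8.05. The mean ratio over both treatments was 8.82-fold. These levels follow the titles in every array, not the genotype tag. The log2 change was -2.82 (SE 0.27) with dsDNA and -3.15 (SE 0.27) without. As the 1 gene named beforehand, Sting had an unadjusted limma p of 0.000104 with dsDNA, 5.87e-05 without and 1.29e-05 on the mean. The difference with dsDNA itself was 0.07 (SE 0.27) in control cells and 0.41 (SE 0.27) in RNAi cells, neither past the threshold.

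**Figure D2:**
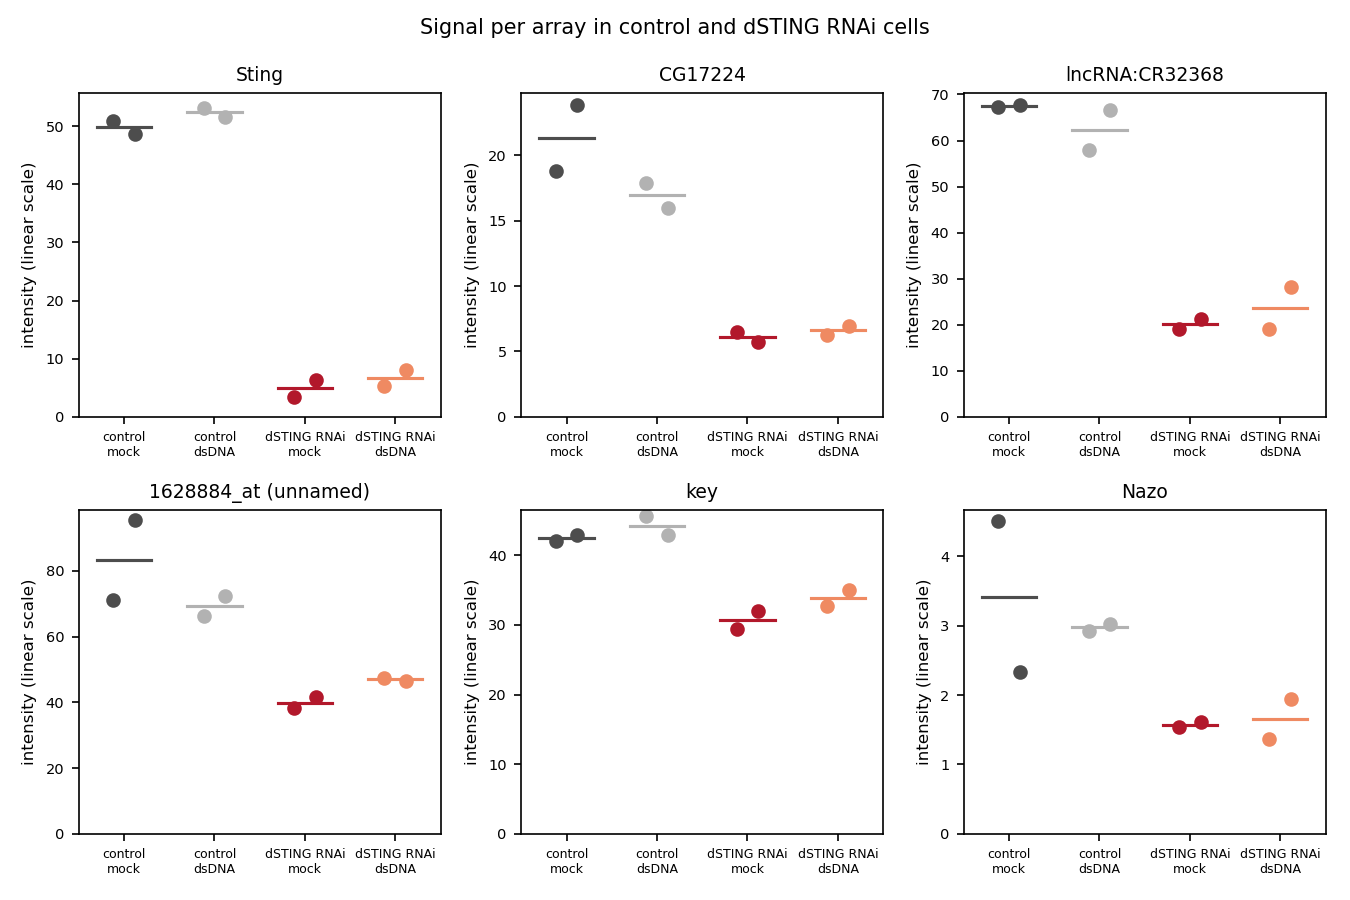
Intensity on a linear scale of Sting, CG17224, lncRNA:CR32368, a probe set with no gene name, key and Nazo in each array, with points for arrays and lines for the means of the 4 groups. The 4 RNAi arrays lie below the 4 control arrays in each panel, and for Sting they lie at 3.45 to 8.05 against 48.7 to 53.1.

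In dsDNA-treated cells, the comparison the series names as its goal, dSTING RNAi lowered Sting 7.83-fold. CG17224, a protein-coding gene, was 2.56-fold lower, with an intensity of 17.0 ± 1.36 in control and 6.62 ± 0.45 in RNAi cells (SD, n = 2 each). lncRNA:CR32368, a long non-coding RNA, was 2.64-fold lower, at 62.3 ± 6.02 against 23.6 ± 6.51 (SD, n = 2 each). No gene lay this far in the other direction: among the 4189 probe sets above the level of 3, these 3 alone differed by 2-fold or more, and the median absolute log2 change was 0.06. Over all 18769 probe sets limma called 0 higher and 0 lower. Sting had an unadjusted limma p of 0.000104 and, adjusted over all of them, 0.901. In all, 847 probe sets had an unadjusted p under 0.05 (447 higher, 400 lower) where chance gives 938. eBayes with trend and robust options also called 0. Tested alone, the probe sets above the level of 3 had 48 unadjusted p under 0.05, where chance gives 209. For the knockdown in mock there were 57 and for the mean knockdown 73. The cause of this deficit was not tested. When probe sets below the median level were left out, as set beforehand, limma called the same 3 genes, with adjusted p of 0.00397 for Sting, 0.0226 for CG17224 and 0.0408 for lncRNA:CR32368. Above the level of 3 their adjusted p were 0.00524, 0.0229 and 0.0398, and there the calls depended on which arrays were kept, while each change stayed negative: with 1 array left out Sting had -3.08 to -2.56, CG17224 -1.31 to -1.16 and lncRNA:CR32368 -1.66 to -1.11. None was called without control dsDNA number 1 or number 2 (Sting, 0.246 and 0.224), only Sting without either dSTING RNAi mock array or dSTING RNAi dsDNA number 1, and only Sting and CG17224 without either control mock array.

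The other genes with the smallest p in this comparison did not pass the threshold, and most were dim. The homeobox gene al had a log2 difference of -0.44 (SE 0.05), the small GTPase gene Rab27 -0.30 (SE 0.04), CG33093 -0.24 (SE 0.03) and Tmtc3, which encodes an O-mannosyltransferase, -0.34 (SE 0.05). On the other side were Regnase-1, an endoribonuclease gene, at 0.29 (SE 0.04), the homeobox gene Ptx1 at 0.34 (SE 0.05) and DopEcR, a receptor for dopamine and ecdysone, at 0.18 (SE 0.03). Of these 7 only Tmtc3 had a mean log2 level above 3, with an intensity of 15.3 ± 0.20 in control and 11.9 ± 0.65 in RNAi cells (SD, n = 2 each). With the filter on that level its SE was 0.096 (unadjusted limma p 0.00678).

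Genes around STING were the 1 list of 27 that camera called in dsDNA-treated cells, and the list holds Sting itself, so the call includes the knockdown itself. Its 9 measured members had a mean log2 change of -0.44 and a median of -0.08 (adjusted p = 0.00052), and adjusted p = 0.541 with an estimated correlation. Without Sting the other 8 had a mean of -0.15 and were not called (adjusted p = 0.0552), and camera called 0 lists. Adjusted over the list alone, 2 members passed: Sting (0.000939) and key, the IKK gamma gene of the Imd pathway (-0.38, SE 0.06; 0.00511). No member passed over all probe sets. The rest of the list had smaller or less certain values: the NF-kappaB gene Rel had -0.15 (SE 0.09), Nazo, an antiviral gene described downstream of Sting, -0.59 (SE 0.24), and IKKbeta 0.04 (SE 0.18). The receptor genes cGlr1 and cGlr2 and the STING-regulated genes Srg1 and Srg2 lay near the floor, with at most 1.48 in any array. The call was lost without control dsDNA number 2 or dSTING RNAi dsDNA number 1 (highest adjusted p 0.197).

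No immune list beyond this one was called in dsDNA-treated cells with all arrays. All 10 measured antimicrobial peptide genes were near the floor, the highest value being 3.76 for Drs, and their mean log2 difference was 0.01. AttD had -0.19 (SE 0.06) and DptB 0.15 (SE 0.05), and 0 passed adjusted over the list alone. The 18 Imd genes had a mean of -0.04, with key passing adjusted over the list alone (0.0205) and PGRP-LE at 0.23 (SE 0.11). The 15 Toll genes had a mean of 0.03 (pll -0.27, SE 0.09; Traf6 0.15, SE 0.11), and the 13 JAK/STAT genes 0.02 (Su(var)2-10 0.19, SE 0.05; dome 0.13, SE 0.09). The 28 hemocyte markers had a mean of -0.02 (Sr-CI 0.06, SE 0.04; PPO2 -0.10, SE 0.09), and 0 members of these 3 lists passed adjusted over the list alone. With all arrays the adjusted p was 0.881 for JAK/STAT genes and hemocyte markers (adjusted p = 0.983 with an estimated correlation), but fewer arrays brought calls: JAK/STAT genes at 0.15 without dSTING RNAi dsDNA number 1 (adjusted p 0.0426), and hemocyte markers at -0.08 without the 2 arrays that stood apart (0.0262). RNA interference genes had a mean of 0.10 over 17 genes, led by drosha at 0.30 (SE 0.10) and aub at 0.19 (SE 0.09), with an adjusted p of 0.142.

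Stress, growth and metabolic genes showed small means in dsDNA-treated cells. DNA damage and p53 genes had 0.04 (Irbp 0.21, SE 0.08; Corp 0.16, SE 0.08), JNK and stress genes 0.02 (p38c 0.17, SE 0.10), and nucleic acid degradation and nucleotide genes -0.03 (Gart 0.13, SE 0.06). Heat shock genes had -0.04 (DnaJ-1 -0.09, SE 0.09; Hsp68 0.11, SE 0.10), unfolded protein response genes 0.01 (Sec61alpha -0.23, SE 0.06; Herp 0.27, SE 0.11), autophagy and lysosome genes 0.01 (cathD -0.06, SE 0.03), apoptosis genes -0.01 (Debcl -0.20, SE 0.12) and cell cycle genes 0.01 (thr 0.18, SE 0.05; Mcm6 -0.20, SE 0.07). The 41 measured ribosomal protein genes, of 93 listed, had 0.01 (RpS19b 0.37, SE 0.11) and the 40 proteasome genes -0.03 (Prosalpha6T 0.21, SE 0.04). The 15 glycolysis genes had 0.01 (tobi 0.14, SE 0.04) and the 67 mitochondrial respiration genes 0.03 (ND-20L -0.10, SE 0.06). With all arrays the proteasome and mitochondrial lists were not called (adjusted p 0.367 and 0.434, and for both adjusted p = 0.983 with an estimated correlation), but single arrays moved their means. Without dSTING RNAi dsDNA number 1 proteasome genes had -0.13 and were called (adjusted p 6.95e-06), as they were above the level of 3 (-0.04, 0.0422). Without dSTING RNAi dsDNA number 2 mitochondrial genes had 0.09 and were called (0.00185). Lipid synthesis and storage had 0.01 (Agpat1 0.12, SE 0.05), detoxification and oxidative stress 0.03 (Cyp12a4 -0.16, SE 0.07) and the ecdysone response 0.01 (Hr39 0.22, SE 0.11). Among markers of other cell types the means were 0.03 for fat body, -0.01 for muscle, 0.08 for neurons and glia, 0.00 for germline and follicle and -0.02 for gut. One of their members, the lipid transfer particle gene Apoltp, rose by 0.32 (SE 0.07) adjusted over the list alone (0.0494), at an intensity of 4.86 ± 0.08 in control and 6.34 ± 0.13 in RNAi cells (SD, n = 2 each). In 6 lists with a mean between -0.01 and 0.03 the mean, the median and the direction of the test differed in sign. Fry called 0 lists.

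In mock-treated cells the knockdown gave the same 3 genes the largest falls. Sting was 10.2-fold lower, CG17224 3.5-fold (log2 -1.65, SE 0.13) and lncRNA:CR32368 3.35-fold (-1.70, SE 0.19). A probe set with no gene name, singled out after its values were seen, had -1.03 (SE 0.14), and key had -0.45 (SE 0.06), a ratio of 1.38. Over all probe sets limma called 0 (smallest adjusted p 0.367), eBayes with trend and robust options 0, and 886 had an unadjusted p under 0.05 (398 higher, 488 lower). With probe sets below the median level left out limma called 3, with adjusted p of 0.00147 for Sting, 0.00191 for CG17224 and 0.00747 for lncRNA:CR32368. Above the level of 3, Sting passed whichever array was left out, CG17224 was lost without dSTING RNAi mock number 2 (0.0600), and lncRNA:CR32368 was lost without control mock number 2 or any single control dsDNA or dSTING RNAi mock array (0.0529 to 0.156).

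The remaining genes with the smallest p in mock-treated cells did not pass over all probe sets. CkIIalpha-i1, an interactor of casein kinase II, had -0.40 (SE 0.03), with mean intensities of 2.94 in control and 1.99 in RNAi cells. Fmr1, an RNA-binding protein gene, had 0.34 (SE 0.04) and mod(mdg4), a chromatin protein gene, 0.28 (SE 0.04), both near the floor. inaF-C (0.23, SE 0.03), Osi9 (0.22, SE 0.03) and CG4546 (0.20, SE 0.03) were at the floor in most arrays. The NaPi-III transporter gene, named after its values were seen, had 1.02 (SE 0.71) with a wide spread between arrays, at 12.3 ± 9.96 and 22.2 ± 3.85 (SD, n = 2 each).

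Of the lists, camera called 2 in mock-treated cells over all probe sets. The STING list had a mean of -0.51 and a median of -0.06 (adjusted p = 0.000995), and adjusted p = 0.606 with an estimated correlation. Sting carried most of this, and the other 8 members had a mean of -0.18 (adjusted p = 0.041), and adjusted p = 0.712 with an estimated correlation. All 9 members had negative values, with Sting and key passing adjusted over the list alone (0.000529 and 0.00212), and key also among Imd genes (0.00848). Mitochondrial respiration genes fell by 0.05 on the mean, with 51 of 67 negative (adjusted p = 0.0278), and adjusted p = 0.975 with an estimated correlation. The call was lost with probe sets below the median level left out (0.136) and without control mock number 2 or either dSTING RNAi mock array (highest 0.471). No mitochondrial gene passed adjusted over the list alone. The mitochondrial mean was -0.02 without the 2 arrays that stood apart (adjusted p 0.793), and the STING mean was -0.56 (0.0620). Above the level of 3 camera called the STING list and 4 others: proteasome (-0.10, adjusted p 0.00977), ecdysone response (0.21, 0.00977), unfolded protein response (0.07, 0.0257) and detoxification genes (0.07, 0.0264). Over all probe sets none of these 4 was called, and each had adjusted p = 0.975 with an estimated correlation. With the filter at the median level camera called proteasome (-0.09, adjusted p 0.0386) and unfolded protein response genes (0.08, 0.0476). PGRP-LB, an Imd pathway amidase gene near the floor, was 0.21 higher (SE 0.04; 0.0129 adjusted over the list alone), the lysosomal protease gene cathD fell by 0.15 (SE 0.03; 0.0485), and bgcn, a germline marker near the floor, had 0.20 (SE 0.04; 0.0265). Fry called 0 lists.

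Averaged over both treatments, with 4 arrays on each side, dSTING RNAi lowered Sting by 2.99 on the log2 scale (SE 0.19), lncRNA:CR32368 by 1.54 (SE 0.13, 2.97-fold) and CG17224 by 1.44 (SE 0.09, 3.01-fold). key had -0.42 (SE 0.04), with 42.5 ± 0.58 and 44.3 ± 1.91 in the control groups and 30.8 ± 1.84 and 33.8 ± 1.65 in the RNAi groups (SD, n = 2 each). The probe set with no gene name had -0.79 (SE 0.10), and Dci, an enoyl-CoA isomerase gene, -0.36 (SE 0.05). Tmtc3 had -0.24 (SE 0.03), CG31436 -0.42 (SE 0.06), CkIIalpha-i1 -0.18 (SE 0.02), the cuticle gene Cpr66Cb -0.18 (SE 0.02) and Regnase-1 0.20 (SE 0.03). Over all probe sets limma called 0 (smallest adjusted p 0.121), with 893 at an unadjusted p under 0.05 (420 higher, 473 lower). With probe sets below the median level left out it called 4: Sting (0.000107), CG17224 (0.000287), lncRNA:CR32368 (0.00084) and the unnamed probe set (0.0439). eBayes with trend and robust options called the first 3 of these over all probe sets, median centring Sting and CG17224, log2(intensity + 16) only Sting, and the 2-group model those 3 genes and Cpr66Cb, while quantile normalization called 0 (Sting, 0.167). Above the level of 3 those 3 passed whichever array was left out, while the unnamed probe set, at 0.0405 with all arrays, passed only without control mock number 1 (0.0066) and had 0.0503 to 0.457 without any other array.

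**Figure D3:**
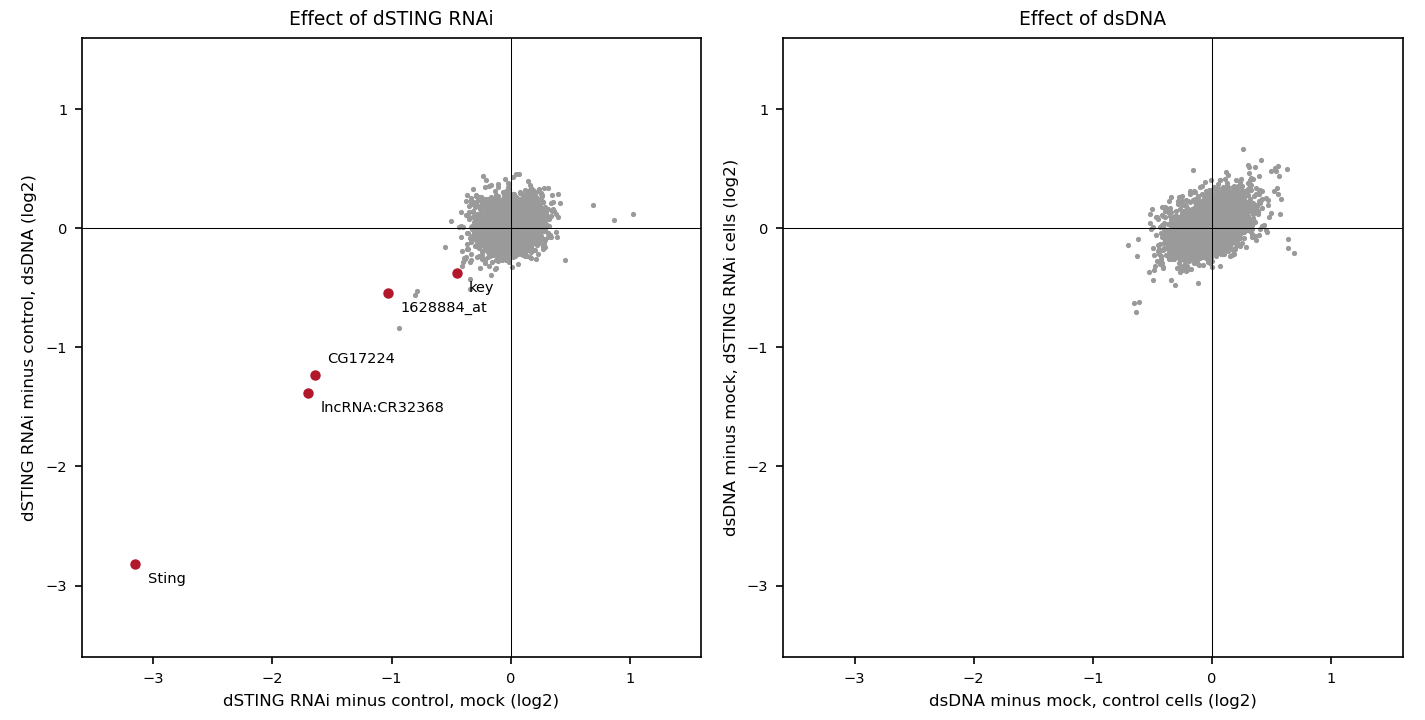
Each grey point is a probe set with a mean log2 level above 3, 4189 in all. The left panel plots the log2 effect of dSTING RNAi without dsDNA on the x axis against that with dsDNA on the y axis, and the right panel the log2 effect of dsDNA in control cells against that in RNAi cells. Sting, at -3.15 and -2.82, CG17224 and lncRNA:CR32368 lie far from the rest on the left, and no probe set reaches 1 on either axis on the right.

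Among lists in the mean knockdown effect, STING genes had a mean of -0.48 and a median of -0.06, with 8 of 9 negative (adjusted p = 2.7e-05), and adjusted p = 0.345 with an estimated correlation. Fry called this list alone (adjusted p = 0.0403). Without Sting the other 8 had a mean of -0.17 and were called by camera (adjusted p = 0.00724), with adjusted p = 0.529 with an estimated correlation and 0.165 by fry. Adjusted over the list alone, 3 members passed: Sting (0.000116), key (0.000576) and Nazo (-0.66, SE 0.17; 0.0320). Nazo was dim, at 3.42 ± 1.54 and 2.98 ± 0.06 in the control groups and 1.58 ± 0.05 and 1.66 ± 0.40 in the RNAi groups (SD, n = 2 each). Proteasome genes fell by 0.05 on the mean, with 34 of 40 negative (adjusted p = 0.0206), and adjusted p = 0.964 with an estimated correlation. No proteasome member passed adjusted over the list alone. Without the 2 arrays that stood apart the proteasome mean was 0.01 (adjusted p 0.775), and its call was lost when any 1 of the 4 arrays numbered 2 was left out. In other lists, key passed among Imd genes (0.0023) and cathD fell by 0.11 (SE 0.02; 0.0481 adjusted over the list alone).

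With dsDNA in control cells no probe set of the 4189 brighter ones differed by 2-fold. CkIIalpha-i1 had -0.42 (SE 0.03) and TMEM216, a ciliary transition zone gene, -0.35 (SE 0.05). The xylosyltransferase gene Xxylt had -0.25 (SE 0.04), AIMP2, a scaffold of the tRNA synthetase complex, -0.21 (SE 0.03) and CG9953 -0.19 (SE 0.03). These SEs depend on the filter. With the filter on a level above 3 they were 0.094, 0.092 and 0.092 for Xxylt, AIMP2 and CG9953. The unadjusted limma p were then 0.0256, 0.0549 and 0.0665. Pdk, which encodes pyruvate dehydrogenase kinase, had 0.41 (SE 0.06), from 4.71 ± 0.27 to 6.60 ± 0.01 (SD, n = 2 each). CG34429 had 0.28 (SE 0.04), CG33093 0.24 (SE 0.03) and the gustatory receptor genes Gr36c and Gr47b 0.22 (SE 0.03) and 0.19 (SE 0.03), all near the floor. None passed over all probe sets: limma called 0 (smallest adjusted p 0.706), and 986 had an unadjusted p under 0.05 (435 higher, 551 lower), where chance gives 938. The filters on dim probe sets and eBayes with trend and robust options called 0 as well. The median half-width of the 95% interval was 0.29 on the log2 scale for brighter probe sets, so small responses can be missed with 2 arrays per group.

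No immune list was called with dsDNA in control cells over all probe sets. JAK/STAT genes had a mean of 0.11, with 10 of 13 positive (adjusted p 0.264), and above the level of 3 they were called at 0.19 (0.0214), while over all probe sets they had adjusted p = 0.88 with an estimated correlation. Above that level camera also called lipid synthesis and storage genes (0.10, adjusted p 0.0214), and it did not call mitochondrial respiration genes. Toll genes had a mean of 0.05 and Imd genes -0.02. DptB, an antimicrobial peptide gene, fell by 0.28 (SE 0.05; 0.0208 adjusted over the list alone), between mean intensities of 1.66 and 1.19, close to the floor. The other 9 measured antimicrobial peptide genes did not pass. Proteasome genes fell by 0.11 on the mean, with 32 of 40 negative (adjusted p = 0.0027), and adjusted p = 0.88 with an estimated correlation; Rpn12 had -0.30 (SE 0.08) and Rpt2 -0.18 (SE 0.08). Mitochondrial respiration genes fell by 0.07, with 54 of 67 negative (adjusted p = 0.0027), and adjusted p = 0.88 with an estimated correlation. No member of these lists passed adjusted over the list alone. Control mock number 2 is one of the arrays that stood apart, and without it both calls were lost, as was the proteasome call without control dsDNA number 1 and the mitochondrial call without control dsDNA number 2. Without both arrays that stood apart, the means were -0.08 (adjusted p 0.0202) and -0.04 (0.252), and with probe sets below the median level left out the mitochondrial call was lost (0.0643). The germline marker bgcn passed adjusted over the list alone (0.19, SE 0.04; 0.0315), and fry called 0 lists.

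In dSTING RNAi cells dsDNA gave no call either. CG31038 had 0.41 (SE 0.07), from an intensity of 8.19 ± 0.21 to 11.2 ± 0.25 (SD, n = 2 each). Of the 10 genes with the smallest p it alone had a mean log2 level above 3. The others were CG14302 (0.22, SE 0.03), the receptor tyrosine kinase gene Tie (0.22, SE 0.03), DopEcR (0.18, SE 0.03), CG13023 (-0.26, SE 0.04), lncRNA:CR42862 (-0.26, SE 0.04), Osi9 (-0.22, SE 0.03), mod(mdg4) (-0.22, SE 0.04), inaF-C (-0.20, SE 0.03) and CG4546 (-0.20, SE 0.03). limma called 0 (smallest adjusted p 1), as did its trend and robust options and both filters, and 820 probe sets had an unadjusted p under 0.05 (412 higher, 408 lower).

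Among lists in dSTING RNAi cells, RNA interference genes rose by 0.11 on the mean with dsDNA, with 15 of 17 positive (adjusted p = 0.0158), and adjusted p = 0.674 with an estimated correlation. Its leading members were mael at 0.16 (SE 0.08) and rhi at 0.10 (SE 0.06). Of its 17 genes, 6 had a mean log2 level above 3. Above that level camera still called the list (0.14, adjusted p 0.0475), and it called glycolysis genes as well (-0.10, 0.0475). Proteasome genes fell by 0.07, with 33 of 40 negative (adjusted p = 0.0158), and adjusted p = 0.794 with an estimated correlation; Rpn8 had -0.17 (SE 0.09) and Prosbeta5 -0.19 (SE 0.10). Without the 2 arrays that stood apart the proteasome mean was 0.02 (adjusted p 0.555) and the RNA interference mean 0.11 (0.0653). The proteasome call was also lost without dSTING RNAi mock number 1, and the RNA interference call without either dSTING RNAi mock array or dSTING RNAi dsDNA number 1. Adjusted over the list alone, NimC1, a phagocytosis receptor gene of hemocytes, fell by 0.44 (SE 0.07; 0.0397), Su(var)2-10, a SUMO ligase gene, rose by 0.29 (SE 0.05; 0.0194) and PGRP-LB fell by 0.20 (SE 0.04; 0.0320). JAK/STAT and Toll genes were not called with all arrays (0.09 and 0.10, adjusted p = 0.186 each, and adjusted p = 0.794 with an estimated correlation). Without dSTING RNAi dsDNA number 1 the first were called (0.22, adjusted p 0.00345), and without dSTING RNAi mock number 2 the second (0.16, 0.0127). Fry called 0 lists.

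Averaged over control and RNAi cells, 3 of the 27 lists held a member that passed adjusted over the list alone. Among hemocyte markers NimC1 was 0.39 lower with dsDNA on the log2 scale (SE 0.05). Its adjusted limma p was 0.0132 over that list alone and 0.894 over all probe sets. Its intensity was 12.01 ± 1.22 and 12.4 ± 0.50 in the mock groups and 9.26 ± 0.19 and 8.89 ± 0.35 in the dsDNA groups (SD, n = 2 each). DptB fell by 0.22 (SE 0.04; 0.0125 adjusted over the list alone), and the muscle gene Mlc2, near the floor, rose by 0.16 (SE 0.03; 0.0351). Over all probe sets none passed. CkIIalpha-i1 had -0.20 (SE 0.02), AIMP2 -0.14 (SE 0.02), the oxidoreductase gene Wwox -0.19 (SE 0.03), CG31038 0.33 (SE 0.05) and Pdk 0.29 (SE 0.04). With the filter on a level above 3 the SEs of AIMP2, Wwox and CG31038 were 0.065, 0.067 and 0.073. The dim genes CG42249 (-0.17, SE 0.02), CG13023 (-0.17, SE 0.03), Cpr65Ea (-0.18, SE 0.03) and CG10339 (0.15, SE 0.02) completed the 10 with the smallest p. limma called 0 (smallest adjusted p 0.894), its trend and robust options 0, and 1009 probe sets had an unadjusted p under 0.05 (475 higher, 534 lower). Proteasome genes fell by 0.09, with 33 of 40 negative (adjusted p = 0.000191), and adjusted p = 0.662 with an estimated correlation. Rpn12 had -0.19 (SE 0.06) and Prosbeta5 -0.22 (SE 0.07), and 0 members passed adjusted over the list alone. The call was lost without dSTING RNAi dsDNA number 2 (0.0689) and without both arrays that stood apart, where the mean was -0.03 (adjusted p 0.378). JAK/STAT genes, at 0.10, and Toll genes, at 0.08, were not called with all arrays (adjusted p 0.0579 and 0.271, and for both adjusted p = 0.662 with an estimated correlation). Leaving out dSTING RNAi dsDNA number 1 (0.17), control mock number 1 (0.14) or dSTING RNAi mock number 2 (0.12) brought a JAK/STAT call. Either of the last 2 brought a Toll call (0.11 each). Lists outside immunity moved as well. Mitochondrial respiration genes were called lower without dSTING RNAi dsDNA number 1 (-0.06), control dsDNA number 1 (-0.05) or control mock number 1 (-0.05). Lipid synthesis and storage genes were called higher without control mock number 1 (0.08). Fry called 0 lists.

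Whether the response to dsDNA depended on the knockdown was tested as the interaction. CkIIalpha-i1 had an interaction of 0.43 (SE 0.05), with 2.94 in control mock cells and 1.95 to 2.02 in the other groups. TMEM216 had 0.46 (SE 0.07), CG2258 0.60 (SE 0.09), Tie 0.32 (SE 0.04) and the tetraspanin gene Tsp42Eo 0.29 (SE 0.04). On the other side were al (-0.46, SE 0.07), mod(mdg4) (-0.39, SE 0.05), CG14770 (-0.36, SE 0.06), dpr4 (-0.33, SE 0.05) and gom (-0.26, SE 0.04). The mean log2 levels of all these genes did not exceed 3, and Tie, Tsp42Eo, mod(mdg4), CG14770, dpr4 and gom lay near the floor. None passed: limma called 0 (smallest adjusted p 1), as did its trend and robust options and both filters, and 786 probe sets had an unadjusted p under 0.05 (389 higher, 397 lower). The median half-width of the 95% interval was 0.41 for brighter probe sets.

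For lists, the interaction was positive for RNA interference genes, with a mean of 0.19 and 15 of 17 positive (adjusted p = 0.00628), and adjusted p = 0.448 with an estimated correlation. vret, a piRNA pathway gene, had 0.60 (SE 0.25) and drosha, the microRNA-processing enzyme gene, 0.33 (SE 0.15). Most of this list was dim, with 6 of 17 genes at a mean log2 level above 3. Mitochondrial respiration genes had a mean of 0.08, with 50 of 67 positive (adjusted p = 0.0132), and adjusted p = 0.967 with an estimated correlation. No member of any list passed adjusted over the list alone, and fry called 0 lists. The RNA interference call was lost without dSTING RNAi mock number 1 or dSTING RNAi dsDNA number 2 (highest adjusted p 0.0707), and the mitochondrial call without 4 of the 8 arrays (highest 0.873). Above the level of 3 camera called 0 lists.

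Across genes, the 2 knockdown effects, which share no array, correlated weakly: Pearson's r was 0.18 and Spearman's rho 0.05 over 11983 genes, and r was 0.08 when the genes called under any filter were left out. The 2 dsDNA effects had an r of 0.28 and a rho of 0.21. Genes are not independent replicates, so no p-value is given. Without dSTING RNAi dsDNA number 2, r was -0.07 for the knockdown effects and -0.16 for the dsDNA effects. Without both arrays that stood apart it was 0.19 and 0.01. Over all probe sets limma called none in either comparison of a pair. With probe sets below the median level left out, the 3 genes called in the knockdown with dsDNA, Sting, CG17224 and lncRNA:CR32368, were also the 3 called in mock.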

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

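The tests of the 3 lowered genes and of the unnamed probe set against the 2 arrays that stood apart, of Sting against the genotype tag, of the first principal component against 3' to 5' signal and spiked-in controls, of the dsDNA correlation and the proteasome list without those arrays, of lists above the level of 3, and of the splits without Sting were chosen only after the result was seen.

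For 2 gene lists camera at the preset correlation called an interaction, a different response to dsDNA in control and dSTING RNAi cells, and with an estimated correlation neither was called (adjusted p = 0.448 and 0.967). RNA interference genes had a mean interaction of 0.188, from -0.08 in control and 0.11 in RNAi cells. Mitochondrial respiration genes had 0.077, from -0.07 and 0.01. Above the level of 3, where 6 of the 17 RNA interference genes lay, camera called 0 lists. The mitochondrial call was lost with the filter at the median level (adjusted p 0.311). Without the 2 arrays that stood apart the RNA interference mean was 0.21 (adjusted p 0.0494) and the mitochondrial mean 0.11 (0.000993). No outlier test was made of single arrays, since each group holds 2.

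The first pattern weighed is the lower signal of Sting, CG17224 and lncRNA:CR32368 after dSTING RNAi. Without the 2 arrays that stood apart, 3 of these 3 genes passed in the mean knockdown effect above the level of 3, with log2 changes of -3.13, -1.39 and -1.68, and 0 arrays had Sting on the wrong side for their title. The 10 neighbours of each gene were not lowered as a group: their mean lay at percentile 18 for Sting, 41.2 for CG17224 and 47.7 for lncRNA:CR32368 among 3537 genes compared. The labels hold 1 knockdown and do not give the dsRNA sequence, so an effect of losing dSTING and an off-target effect of its dsRNA both stay open for the genes other than Sting. For the unnamed probe set the change went from -0.788 (SE 0.102) to -0.675 (SE 0.084) without those arrays and its call ended (adjusted p 0.0947) on 6 arrays, but it stayed beyond 2 SE of 0, so by its size those arrays are not the whole source, although the criterion first set also asked for an adjusted p of 0.05 or less and was relaxed after the value was seen.

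The mean knockdown effect was set against the 35 splits of the 8 arrays into 4 and 4. With a 2-group model over all probe sets the real split called 4 and the highest other 0, and above the level of 3 also 4 against 0, with 1 of 35 splits reaching the real count each time. These counts hold Sting, the target itself. Without Sting the real split called 2 in each and the highest other 0, again 1 of 35 splits each time. With 35 splits no smaller share is possible, and this count was chosen after the first was seen. It therefore cannot exclude chance for the other probe sets. For lists it called 2 against a highest other of 6, 13 splits giving as many, so chance cannot be excluded. For dsDNA the real split called 0 over all probe sets and 0 above the level of 3, where the highest other, 4 in each, was the knockdown split itself, and since any of the 35 splits reaches a count of 0, this says nothing on chance. It called 1 list against a highest other of 6, with 23 splits as large, so chance cannot be excluded. Splits that part the 2 arrays that stood apart called a median of 1.5 lists and those that keep them together 0, which points to a structure of the arrays in the list tests.

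The second pattern is that structure, the first principal component. Its score correlated with the 3' to 5' signal of control transcripts at r = -0.89 (exact permutation p = 0.00392, adjusted p = 0.0118 over 3 measures, n = 8 arrays), but at -0.65 (exact p = 0.14) over the 6 arrays left without the 2 farthest from the median of that measure, which are the 2 that stood apart. Spiked-in hybridisation controls gave r = 0.41 (exact p = 0.327) and the share of probe sets at the floor -0.54 (exact p = 0.152). Over 6 arrays, without the 2 farthest from the median of the measure, these were 0.54 (exact p = 0.272) and -0.82 (exact p = 0.0375), so a relation stays open for both. RNA integrity or labelling is a candidate source that cannot be told apart from others here, because 2 arrays carry most of the component. No biological explanation was tested, since the 2 arrays belong to different groups.

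The third pattern is the likeness of the 2 dsDNA effects and the lower proteasome genes. Over genes above the level of 3 the correlation was 0.464 with all arrays and 0.011 without the 2 that stood apart. The proteasome mean over control and RNAi cells went from -0.09 to -0.03 (adjusted p 0.378), so that both may reflect those arrays. In control cells alone, however, the proteasome mean went only from -0.11 to -0.08 and stayed called (adjusted p 0.0202; 0.281 without control mock number 2 alone). With all arrays it had adjusted p = 0.88 with an estimated correlation, so a response to dsDNA is open there and not shown.

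Without the 2 arrays camera, at the preset correlation, also called unfolded protein response genes lower (-0.09, adjusted p 0.00389, on the mean and -0.12, 0.00398, in RNAi cells) and, in RNAi cells, mitochondrial respiration (0.07, 0.0141) and cell cycle genes (0.08, 0.0318) higher. None of these was called with all arrays, with adjusted p = 0.812 for the first and 0.794, 0.98 and 0.794 for the others with an estimated correlation. The mean proteasome interaction, not called with all arrays, was 0.10 without the 2 arrays and 0.125 without dSTING RNAi dsDNA number 2 alone. Camera called it in both of these settings, each of which leaves a group with 1 array.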

How the results depend on the processing

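Chosen only after the result was seen were the tests with the filter on a level above 3, without the 2 arrays that stood apart, with the residual component, with the crossed block and with lists without Sting, and those that left out an array for lists and correlations or together with that filter.

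Sting kept its direction in all 30 settings of each knockdown comparison. Its log2 change was weakest with log2(intensity + 16), at -1.59 with dsDNA, -1.66 in mock and -1.63 on the mean. Leaving out 1 array gave -3.08 to -2.56, -3.51 to -2.79 and -3.17 to -2.81. It passed the adjusted threshold in 10, 12 and 16 of the 30.

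Counts of probe sets called by limma were 0 in each of the 7 contrasts over all probe sets, and 0 whichever array was left out. For the knockdown with dsDNA they were 3 with the filter at the median level, 3 with the filter on a level above 3, 3 with that filter without the 2 arrays that stood apart and 3 with it and the residual component. For the knockdown in mock the same settings gave 3, 3, 3 and 6, and for the mean knockdown 4, 4, 3 and 8. The mean knockdown also gave 2 with median centring, 3 with trend and robust, 1 with pseudocount 16 and 4 with the 2-group model. Filters change the count by construction, since fewer probe sets are tested and the variance prior is estimated without those at the floor; for the other settings the cause was not tested. With the level filter and 1 array left out the counts were 0 to 3 with dsDNA (0 without control dsDNA number 1 or 2), 1 to 4 in mock (1 without dSTING RNAi mock number 2, 4 without control mock number 1) and 3 to 5 on the mean (5 without dSTING RNAi dsDNA number 2). A lone array left in a group is assumed to vary like the other groups. The dsDNA comparisons and the interaction had 0 in every setting run.

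The replicate number as a block gave 0 calls in each contrast, with -2.82 for Sting with dsDNA and an adjusted p of 0.488 in the mean knockdown, and the crossed block gave 0 as well. The numbers do not pair the arrays: the 6 correlations between groups of the differences of number 1 and 2 ran from -0.74 to 0.38, with 1 above 0.1. With the block, the lists called were 1, 2, 2, 2, 2, 2 and 1 over the 7 contrasts, as without it.

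Lists called by camera fell to 0 in each of the 7 contrasts with an estimated correlation. fry called 0 in each but the mean knockdown, where it called 1. With the level filter the counts were 2 for the knockdown with dsDNA, 5 for the knockdown in mock and 0 for the interaction. For dsDNA they were 3 in control cells and 3 in RNAi cells. Without the 2 arrays that stood apart they were 3 for the knockdown with dsDNA, 0 in mock, 1 for dsDNA in control cells and 1 for the mean knockdown. With the filter at the median level they were 3 for the knockdown in mock, 1 for dsDNA in control cells and 1 for the interaction. Leaving out 1 array gave 0 to 2 for the knockdown with dsDNA, 1 to 4 in mock, 0 to 2 for dsDNA in control cells, 0 to 5 in RNAi cells, 0 to 3 for the interaction, 1 to 4 for the mean knockdown and 0 to 5 for mean dsDNA. With lists without Sting the count was 0 for the knockdown with dsDNA, where the STING list was the 1 called, because the targeted gene is gone, and as before in the other 6 contrasts. Apart from the lists without Sting, the cause of these changes was not tested.

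The correlation of the knockdown effects was 0.343 with the level filter, 0.366 with it without the 2 arrays that stood apart, and -0.072 to 0.316 with 1 array left out. Without the genes called under any filter the first 2 were 0.126 and 0.231. That of the dsDNA effects was 0.464 with the level filter, 0.008 without the 2 arrays, 0.011 with both, and -0.164 to 0.466 with 1 array left out. Both turned negative without dSTING RNAi dsDNA number 2, and the cause was not tested. DnaJ-1 in the knockdown with dsDNA turned from -0.09 to 0.016 without control dsDNA number 2, the cause was not tested, and its values ran from -0.193 to 0.016 with 1 array left out. Of named genes under alternatives, 3814 values kept direction and side of the threshold and 40 crossed it in the same direction. Signal over background limits the rest: 19.6% to 24.1% of values per array lie at the floor, where no change can be seen.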

Other observations

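Levels in these cells are given as values only. Antimicrobial peptide genes were measured for 10 of 22 listed (45.5%), with a median intensity of 1.24. Among hemocyte markers the ferritin gene Fer1HCH had a mean intensity of 579, Col4a1 218 and SPARC 201, and eater, Hml and lz had 1.04, 2.38 and 1.01. In immune pathways, Stat92E had 32.5 and vir-1 201, and Dif had 1.1 and dl 5.78. In RNA interference, Dcr-2 had 24.9 and Tudor-SN 58.2, while piwi had 1.27.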
